A study of Mus musculus with 8 samples.

How the data were processed

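Gene expression was measured on 8 arrays of primary calvarial osteoblasts from C57Bl/6 mice, 4 labelled Lrp5 knockout and 4 control. Per the labels' protocols, an adenovirus carrying Cre or GFP was added 48 hours ahead of differentiation, and the cells were then kept for 7 days with 50 ug/ml ascorbic acid and 10 mM beta-glycerol phosphate. The labels do not say which group received which virus. RNA was purified on Qiagen RNeasy columns, amplified to biotin-labelled cRNA with an Ambion kit and hybridised to Illumina arrays, per the labels' protocols.

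GenomeStudio is the only tool that the submitters' processing notes name, with no version. Per the file headers, the authors deposited for each array a signal intensity and a detection value for each of 25697 probes. The deposited intensities were on a linear scale and differed between arrays in their median (126 to 155), and the lowest was 91.6, so they were taken as neither normalized nor background-subtracted. The deposited detection column is headed as a p-value but rose with the signal (Spearman correlation of at least 0.979 on each array), so that 1 minus it was used as the detection p-value. A second table that the authors deposited held log2 values with the same median of 6.89 on every array and the same order of probes within each array as the intensities; it was taken as quantile-normalized and used only as an alternative. How its scale was set beyond that is not given in the sources used here.

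The intensities were background-corrected and quantile-normalized with the neqc method of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values and adds an offset of 16, and were put on the log2 scale. Probes with a detection p under 0.01 on at least 4 of the 8 arrays were kept, 10004 in all. The platform annotation gave 1 gene symbol to 23978 probes, several to 0 and none to 1719; 23962 were matched by gene ID to the reference gene table of GRCm38.p6, which changed 0 symbols. No coordinates are given, since the sources used here name no build. Of the probes kept, 9443 had a symbol and 561 did not, and the latter stayed out of the gene tests. For each gene the probe with the highest mean over all arrays was used, which gave 7041 genes, 1761 of them with more than 1 detected probe. Where other detected probes disagree with the named one, that is stated, except for genes first named under the other observations, whose other probes were not compared. A gene not detected on any array of 1 group is given only as a lower bound of its fold change, and a value printed for a gene detected in neither group is a difference between background signals. No array had the values of another (0 of 28 pairs), and the arrays correlated with a mean Pearson r of 0.994 within either group and 0.99 between the groups, over detected probes.

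Knockout-labelled and control arrays were compared with lmFit and eBayes of limma without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are given as knockout-labelled minus control, in log2. The 31 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 genes tested were compared with the camera test of limma at a preset inter-gene correlation of 0.01, adjusted over the 25 lists tested. They were compared again with an estimated correlation and with fry. Camera sets a list against the other genes tested and fry does not, so a pass by fry answers a different question. The number of genes given as measured in a list counts only members that passed the detection filter. Members with no named probe, or whose probes failed the filter, are left out of it. Exact two-sided permutation tests over the 70 assignments of the 8 arrays cannot give a p below 0.0286. The genes named are Lrp5; the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between the groups (236 and 342 were eligible, and 0 predicted genes were passed over); up to 4 members of each list with the smallest p; and a fixed set of fatty acid, Wnt and osteoblast genes, of which Hadha and Runx2 were not analysed here because no probe was named for them.

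The steps were tested on simulated data, 10 runs with 200 of the 7041 genes changed between 4 and 4 arrays. They recovered 23% of genes changed by 0.25 log2, 77% of those changed by 0.5 and 98.5% of those changed by 1, with 4.93% false calls. At an unadjusted camera p under 0.05, a list of 20 genes shifted by 0.2 was called in 100% of runs and an unshifted one in 0%. The simulated genes varied independently of each other, so these list rates do not carry over to lists whose genes vary together. Alternatives tried were no background correction, normexp with an offset of 50, 75th percentile scaling, the authors' log2 table, the replicate number as a block, array weights, other detection filters, the mean of a gene's probes, each probe on its own, a trended and robust prior, other thresholds, other list tests and leaving out each array in turn. Slide as a block was not run, since the files used here name no slides.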

Results

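Primary calvarial osteoblasts, the bone-forming cells of the skull vault, were taken from C57Bl/6 mice and profiled on day 7 of osteogenic differentiation. The 8 arrays fell into 2 groups of 4, labelled Lrp5 knockout and control. Lrp5 is a cell-surface receptor of the LDL receptor family that acts as a coreceptor for Wnt ligands, and the series asks how its loss bears on fatty acid metabolism in the osteoblast. Total RNA was hybridised to Illumina expression arrays with 25697 probes, of which 9685 to 10363 (37.7% to 40.3%) were detected per array. The number detected was 10079 ± 215 in the control group and 9866 ± 204 in the knockout-labelled group (SD, n = 4; exact two-sided permutation p = 0.229). Nothing in the labels says that the arrays of a group came from separate animals or cultures, so the p-values measure the spread between these arrays, which may be technical, and their number limits the precision.

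The first comparison asked whether the transcript of the targeted gene differed between the groups. The single Lrp5 probe stood at 5.54 ± 0.12 log2 in the control arrays and at 5.87 ± 0.26 in the knockout-labelled arrays (SD, n = 4), close to background in both. It was detected on 1 of 4 control and 2 of 4 knockout-labelled arrays. The difference was 0.33 log2 (SE 0.12) toward the knockout-labelled arrays and did not pass the test (limma adjusted p = 0.222; exact two-sided permutation p = 0.0857). The control values were 5.43, 5.70, 5.48 and 5.53, and the knockout-labelled values 5.63, 5.66, 6.07 and 6.10. The position of this probe relative to the deleted part of the gene is not known here, so it does not check the labels, and the directions given below rest on the labels alone. Lrp6, the closest relative of Lrp5, stood at 5.91 ± 0.38 in control and 5.72 ± 0.08 in knockout-labelled arrays (SD, n = 4; limma adjusted p = 0.645), and was detected on 2 control arrays only.

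The second comparison asked which genes differed between knockout-labelled and control osteoblasts. Among genes detected in both groups, the largest fall was that of Cdkn1c, an inhibitor of cyclin-dependent kinases, which was 5.89-fold lower in the knockout-labelled arrays (9.24 ± 0.28 against 6.68 ± 0.35 log2; SD, n = 4; limma adjusted p = 2.81e-05). Cd74, the invariant chain of MHC class II, fell 3.34-fold, and Fabp3, a fatty acid binding protein, fell by a signal ratio of 2.69, which is not an exact fold because it was detected on only 1 of the 4 knockout-labelled arrays. The largest rise among them was that of the gap junction protein Gjb2, 2.79-fold (8.01 ± 0.09 against 9.49 ± 0.17 log2; SD, n = 4; adjusted p = 1.56e-05). Of 7041 genes tested, 607 passed an adjusted p of 0.05, 249 of them higher and 358 lower in the knockout-labelled arrays.

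Most changes were small. Among the genes past the threshold, 17 rose and 65 fell by a signal ratio of at least 1.5. The falls counted include genes undetected on the knockout-labelled arrays, whose lower bound can be smaller, such as 1.31-fold for Olfr229. The median change was 0.36 log2 for the genes that rose and -0.38 for those that fell, against a median residual SD of 0.11. The values of the 2 groups did not overlap for 1182 genes, 16.8% of those tested, where chance gives 2.86%. With each array scaled to a common 75th percentile in place of quantile normalization, 338 genes were higher and 315 lower. With 1 array left out, the count lay between 327 and 722, and it fell by over 1.5 times without control array 1 (370), 2 (327) or 3 (328) and without knockout-labelled array 1 (392), 2 (327) or 3 (390).

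The other large rises lay between 0.68 and 0.94 log2, and whether these genes share functions was not tested. The cytokine Il19 rose by 0.94 log2, the transcription factor Klf4 by 0.89, the stress-activated kinase Mapk14 by 0.86 and Vnn3 by 0.82. Snrpa1, a spliceosome component, rose by 0.75, the granzyme Gzmd by 0.74, the activin-binding protein Fst by 0.73 and the farnesyl diphosphate synthase Fdps by 0.72. Slc40a1, the iron exporter ferroportin, rose by 0.70, the lipocalin Apod by 0.68 and the medium-chain fatty acid receptor Gpr84 by 0.68 (SE 0.14; limma adjusted p = 0.0193), whose call was lost without control array 2 or 3 or knockout-labelled array 1 (adjusted p up to 0.0574). The probes of Klf4 disagreed, since its 2 other detected probes changed by -0.02 and 0.15. Il19 was detected on 2 of 4 control and 4 of 4 knockout-labelled arrays, so its change is not exact.

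Among the other falls, 7 were of genes detected on all 4 control arrays and on none of the knockout-labelled ones, so each has only a lower bound and is not ranked. The bound sets the control mean against, per knockout-labelled array, the higher of the lowest signal among detected probes and the probe's own signal. The taste receptor Tas2r106 was at least 2.4-fold lower, Vpreb1, part of the surrogate light chain of B cell precursors, at least 2.11-fold, and the integrin subunit Itga3 at least 1.87-fold. S100a7a was at least 1.94-fold, Tinagl1 at least 1.67-fold, and the olfactory receptors Olfr372 and Olfr229 at least 1.53-fold and 1.31-fold lower. The limma adjusted p-values of these 7 genes lay between 1.94e-06 for Olfr372 and 0.00181 for S100a7a. Aif1l also fell (2.2-fold) and stayed detected on all 4 knockout-labelled arrays. Tmem51 fell by a signal ratio of 2.27, which is not an exact fold because it was detected on only 3 of them.

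**Figure D1:**
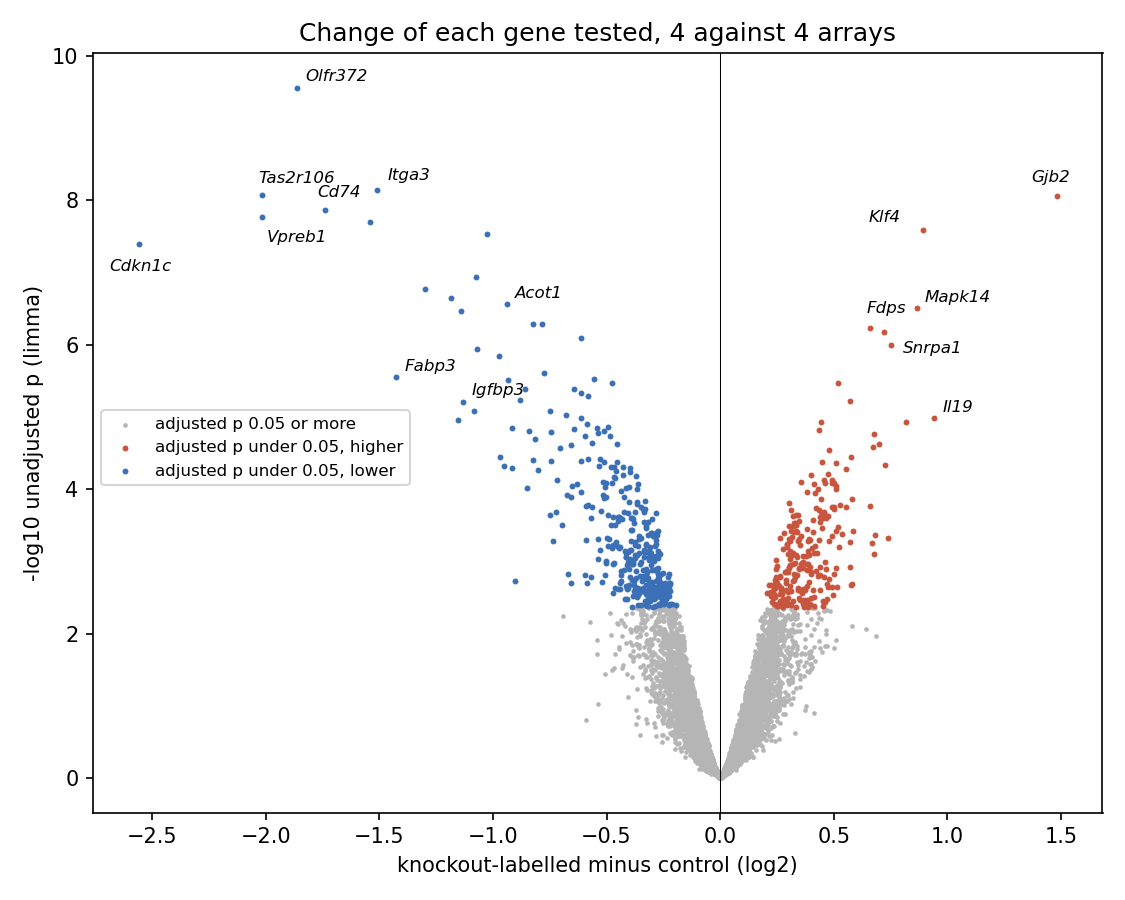
Change of each of the 7041 genes tested, knockout-labelled minus control, in log2 (x axis), against -log10 of the unadjusted limma p (y axis), 4 arrays per group; red and blue points are the 249 higher and 358 lower genes past an adjusted p of 0.05. Cdkn1c lies farthest to the left at -2.56 and Gjb2 farthest to the right at 1.48.

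The third comparison asked whether gene lists fixed before the data were examined moved together, beginning with fatty acid metabolism. Of 16 mitochondrial beta-oxidation genes measured, 1 rose and 1 fell. Acadvl, the very long-chain acyl-CoA dehydrogenase, rose by 0.27 log2 (SE 0.07; limma adjusted p = 0.0353), and Acaa2, the mitochondrial thiolase, fell by 0.41 (SE 0.10; adjusted p = 0.0355). Cpt2 changed by -0.02, Acadl by -0.13 and Acadm by -0.22 without passing the test (adjusted p = 0.874, 0.441 and 0.141), and Cpt1a, the carnitine palmitoyltransferase of the outer membrane, was not detected on any array. The median of the list was -0.09, with 12 of 16 members below 0, and the list did not pass (camera adjusted p = 0.247; 0.482 with an estimated correlation). The calls of Acadvl and Acaa2 were each lost when any of 6 of the 8 arrays was left out (adjusted p up to 0.0857 and 0.0938) and with no detection filter (0.0729 and 0.0788) or a looser filter (0.066 and 0.0652).

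Among the other fatty acid lists, single members changed and no list passed camera, while by fry fatty acid synthesis (adjusted p = 0.00603), peroxisomal oxidation (0.0354) and the PPAR and PGC-1 list (0.0158) did. Fabp3 was the only 1 of 8 uptake and activation genes to change; the list's median was 0.04 and its mean -0.13, opposite in sign, with a camera direction downward (adjusted p = 0.947). Acaa1a, a peroxisomal thiolase, rose by 0.32 (SE 0.06), 1 of 10 peroxisomal genes (list adjusted p = 0.247). Of 9 triglyceride storage and lipolysis genes, Dgat2 rose by 0.26 and the lysosomal lipase Lipa fell by 0.22 (limma adjusted p = 0.0383 and 0.0483; list 0.792). Those 2 calls were lost without any of 6 arrays for Dgat2 and without any of the 8 for Lipa (adjusted p up to 0.102 and 0.125), and both with no detection filter or the looser one, and that of Lipa with 75th percentile scaling. Of 13 fatty acid synthesis genes, 0 passed in limma or when adjusted over the list alone (median 0.12; list adjusted p = 0.104). Acot1, an acyl-CoA thioesterase and PPAR target, fell 1.92-fold (SE 0.08 log2; adjusted p = 0.000137), 1 of 7 PPAR and PGC-1 genes; that list did not pass (adjusted p = 0.256) but did with no detection filter (0.00574) or the looser one (0.0242). Adjusted over the list alone, 1 of the 7 rose and 3 fell.

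At the preset correlation the cholesterol list was higher and the oxidative phosphorylation list lower, and neither passed with an estimated correlation. Of 16 genes of cholesterol synthesis and uptake, 10 rose and 0 fell, 11 when adjusted over the list alone, and all 16 changes were above 0. Fdps rose 1.65-fold, the transcription factor Srebf2 1.42-fold, the sterol demethylase Cyp51 1.37-fold and the sterol transporter Stard4 1.36-fold (limma adjusted p = 0.000235, 0.00578, 0.00947 and 0.00946). The list median was 0.30 (camera adjusted p = 5.4e-09; adjusted p = 0.166 with an estimated correlation). Of 63 oxidative phosphorylation genes, 57 were below 0 and 3 passed, namely the respiratory chain subunits Uqcrh (-0.29) and Ndufb6 (-0.25) and the ATP synthase subunit Atp5j2 (-0.22); adjusted over the list alone 0 passed. The list median was -0.10 (camera adjusted p = 1.77e-05; 0.223 with an estimated correlation). Those 3 calls were lost without any of 4, 7 and 8 of the arrays respectively (adjusted p up to 0.074, 0.0959 and 0.124), all 3 with 75th percentile scaling and with no detection filter or the looser one, and that of Ndufb6 with the mean of its probes.

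The pyruvate dehydrogenase subunit Pdhb fell by 0.54 log2 (SE 0.07; limma adjusted p = 0.00204), and Idh3a of the TCA cycle fell by 0.27 (adjusted p = 0.0329; up to 0.0906 with 1 array left out, the call being lost for 6 of the 8 arrays, and with no detection filter or the looser one). These were 2 of 17 genes of the TCA cycle and pyruvate dehydrogenase list, 3 when adjusted over the list alone (median -0.12; camera adjusted p = 0.00965; 0.223 with an estimated correlation). Of 15 glycolysis genes, the glucose transporter Slc2a1 rose by 0.32 and the hexokinase Hk1 by 0.34 (adjusted p = 0.00998 and 0.0153), 2 also when adjusted over the list alone. That list's median was 0.12 (camera adjusted p = 0.0242; 0.381 with an estimated correlation), and its call was lost without control array 2 (0.0757) or knockout-labelled array 4 (0.0778) and with detection required on all 8 arrays (0.0578). Of 14 hypoxia response genes all were above 0 and 3 rose, 4 when adjusted over the list alone, among them Ak4 by 0.49 and the angiogenic factor Vegfa by 0.33 (adjusted p = 0.0142 and 0.0233). The median was 0.18 (camera adjusted p = 0.000146; 0.223 with an estimated correlation). The call of Vegfa was lost without any of 5 arrays (adjusted p up to 0.0686) and with no detection filter.

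Wnt target genes did not pass as a list. Of 28 canonical targets listed, 27 had a named probe and only 13 passed the detection filter. Among those 13, cyclin D1 (Ccnd1) fell by 0.49 log2 (SE 0.06, limma adjusted p = 0.00204) and 0 rose. Adjusted over the list alone, 2 rose and 2 fell. The median was 0.10 (camera adjusted p = 0.382). The targets Axin2 and Lef1 stood near background, Axin2 being detected on 0 control and 1 knockout-labelled arrays and Lef1 on none. Of 17 Wnt ligands, receptors and modulators, the Wnt cargo receptor Wls rose by 0.30 and the R-spondins Rspo2 and Rspo3 by 0.36 and 0.35, while Wnt5a fell by 0.42 and the receptor Lrp4 by 0.32; the same numbers passed when adjusted over the list alone. The median of that list was 0.02 and its mean -0.00, and it did not pass (camera adjusted p = 0.798). Another detected probe of Wnt5a changed by -0.02, and its call was lost without knockout-labelled array 2 (adjusted p = 0.0557) and with the mean of its probes. Lrp4 was also the only 1 of 7 LDL receptor family genes to pass, also when adjusted over the list alone (limma adjusted p = 0.0339; list 0.909), and lost its call without any of 6 arrays (up to 0.0844), with no detection filter or the looser one and with a trended and robust prior.

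Osteoblast genes were slightly higher as a list at the preset correlation and did not pass with an estimated one, and the only member past the threshold fell. Ank, a transporter that exports the mineralisation inhibitor pyrophosphate, fell by 0.33 log2 (SE 0.06; limma adjusted p = 0.00947). Ibsp changed by 0.58 (SE 0.18, limma adjusted p = 0.07), Sp7 by 0.16, Col1a1 by 0.15 and Alpl by 0.12, none past the threshold. Ibsp was detected on 1 control and 4 knockout-labelled arrays, so its change is not exact. Bglap, which encodes osteocalcin, was not detected on any array. Of the 18 genes, 16 were above 0, and 2 rose and 1 fell when adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.0295; 0.31 with an estimated correlation), and the call was lost without control array 4 (0.0873) or knockout-labelled array 1 (0.0673) or 4 (0.0778), with detection on all 8 arrays (0.074) and by fry (0.0751). Ibsp passed under 4 other settings (adjusted p from 0.0263 to 0.0383) and without control array 2 (0.0133).

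Of 25 extracellular matrix genes, 4 rose, among them tenascin C (Tnc) by 0.31 log2 and thrombospondin (Thbs2) by 0.31 (limma adjusted p = 0.013 and 0.0213), and 6 rose and 1 fell when adjusted over the list alone. The list median was 0.08 (camera adjusted p = 0.0303; 0.4 with an estimated correlation), and its call was lost without control array 2 (0.132) or knockout-labelled array 4 (0.168), with array weights (0.0548) and by fry (0.0645), and so was that of Thbs2 without control array 2 or knockout-labelled array 2 (up to 0.0657). Among 14 insulin and IGF genes, the binding protein Igfbp3 fell 2.19-fold, Igf1 fell 1.25-fold and Igfbp2 rose 1.36-fold (adjusted p = 0.00117, 0.0296 and 0.00183), and 2 rose and 3 fell when adjusted over the list alone. That list did not pass (camera adjusted p = 0.91), and Igf1 lost its call without any of 4 arrays (up to 0.0819) and with no detection filter or the looser one.

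Cell cycle genes were lower as a list in the knockout-labelled arrays at the preset correlation, and did not pass with an estimated one. Of 27 measured, 26 were below 0 and 8 fell, 16 when adjusted over the list alone. The replicative helicase genes Mcm2, Mcm4 and Mcm5 fell 1.63-fold, 1.39-fold and 1.32-fold (limma adjusted p = 0.00293, 0.0176 and 0.0181). The list median was -0.29 (camera adjusted p = 5.4e-09; adjusted p = 0.223 with an estimated correlation). Mcm4 lost its call without control array 2 or 3 or knockout-labelled array 2 (up to 0.0529) and Mcm5 without control array 3 (0.0504). Of 21 p53 and DNA damage response genes, Pmaip1, which promotes apoptosis, was at least 1.5-fold lower and Ccng1 fell by 0.35 log2, 4 falling when adjusted over the list alone (median -0.11; camera adjusted p = 0.0367; 0.223 with an estimated correlation). That call was lost without control array 2 (0.0515) or 4 (0.104) or knockout-labelled array 1 (0.0974), with array weights (0.055), with detection on all 8 arrays (0.0763) and by ranks (0.0528).

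Interferon and inflammatory genes were higher as lists at the preset correlation, and neither list passed with an estimated one. Of 31 interferon response genes, 6 rose and 0 fell, 16 when adjusted over the list alone. The immunoproteasome subunit Psmb9 rose by 0.43 log2, the antiviral gene Ifit2 by 0.46 and the nucleic acid sensor Zbp1 by 0.38 (limma adjusted p = 0.00602, 0.0102 and 0.00637); the other detected probe of Zbp1 changed by -0.02, and its call was lost with the mean of both probes (0.27). The list median was 0.22 (camera adjusted p = 3.8e-08; adjusted p = 0.223 with an estimated correlation). Of 21 inflammatory genes, 5 rose and 0 fell, and 9 rose and 1 fell when adjusted over the list alone. Nos2 rose by 0.67, the cyclooxygenase Ptgs2 by 0.46, the chemokine Ccl5 by 0.40 and the NF-kB inhibitor Tnfaip3 by 0.33, and the list median was 0.20 (camera adjusted p = 0.000379; 0.223 with an estimated correlation). The call of Ptgs2 was lost without any of 4 arrays and that of Ccl5 without control array 2 or 3 (adjusted p up to 0.0814 and 0.0535), and that of Ptgs2 also with no detection filter or the looser one. Beside these, the 8 monocyte, macrophage and osteoclast markers had a median of -0.17.

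Unfolded protein response genes did not pass as a list, with 0 of 18 past the threshold in either adjustment (median 0.06; camera adjusted p = 0.0835), though the list passed without control array 4 (0.0475) or knockout-labelled array 3 (0.0413), with 75th percentile scaling (0.0299), with no filter (0.0495), with the mean of a gene's probes (0.0438) and by fry (0.0303). Of 14 immediate early and heat shock genes, 3 rose, among them Klf4 and Klf2 (0.49 log2), and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.313; 0.0223 by fry).

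Among markers of other cell types, single genes changed. Of 8 monocyte, macrophage and osteoclast markers, Laptm5 fell by 0.47 log2 (limma adjusted p = 0.0042), and 1 (Ctsk) rose and 4 fell, Lyz2 among them, when adjusted over the list alone (camera adjusted p = 0.265). Lyz2, abundant in macrophages, stood at 10.9 and 10.7 log2 in control and knockout-labelled arrays, and Ctsk at 11.7 and 11.9, neither past the threshold, though Lyz2 passed without knockout-labelled array 4 (0.0467) and Ctsk without control array 4 (0.0486), and both without background correction, in the authors' table and with a trended and robust prior. Of 7 smooth muscle and myofibroblast markers 0 passed in limma and 1 fell when adjusted over the list alone (camera adjusted p = 0.382). The remaining 6 lists had fewer than 5 genes measured and were not tested as lists. In them the cartilage collagen Col2a1 rose by 0.45 (1 of 4 chondrocyte genes), the skeletal muscle actin Acta1 fell 1.66-fold (1 of 4 muscle genes) and Egfl7 fell by 0.45 (1 of 3 endothelial genes). None of 1 adipocyte, 2 neural and glial and 3 sex-linked transcripts measured passed. Named probes existed for 14 adipocyte and 18 chondrocyte genes, most of which failed the detection filter.

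In all, 11 of 25 lists tested passed an adjusted camera p of 0.05, 7 of them higher and 4 lower. With a correlation estimated for each list, 0 passed after adjustment and 3 at an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance in 1 direction without setting them against the other genes, 14 passed. That count is not a repeat of the camera result. The array means of 10 lists separated the groups completely, at 0.0286, the smallest p that the exact permutation test can give, which became 0.0714 after adjustment.

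**Figure D2:**
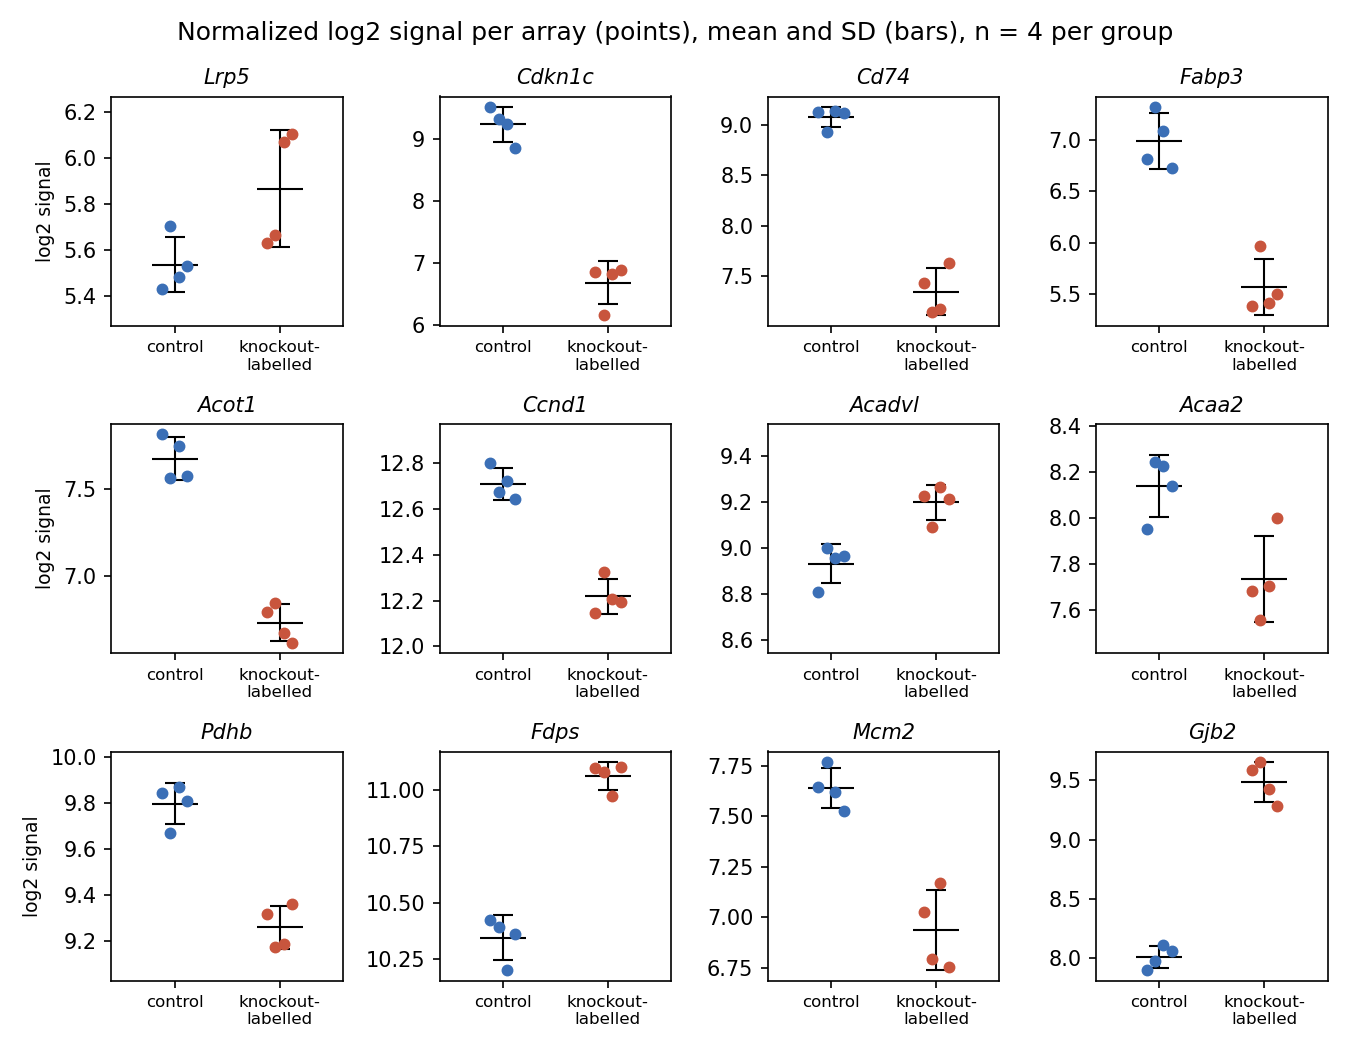
Normalized log2 signal of 12 genes on each array (points), with the mean and SD of each group (bars), n = 4 arrays per group. The groups lie apart for Cdkn1c, Cd74, Fabp3, Acot1, Ccnd1, Acadvl, Pdhb, Fdps, Mcm2 and Gjb2, and overlap for Lrp5 (5.54 ± 0.12 against 5.87 ± 0.26) and Acaa2.

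**Figure D3:**
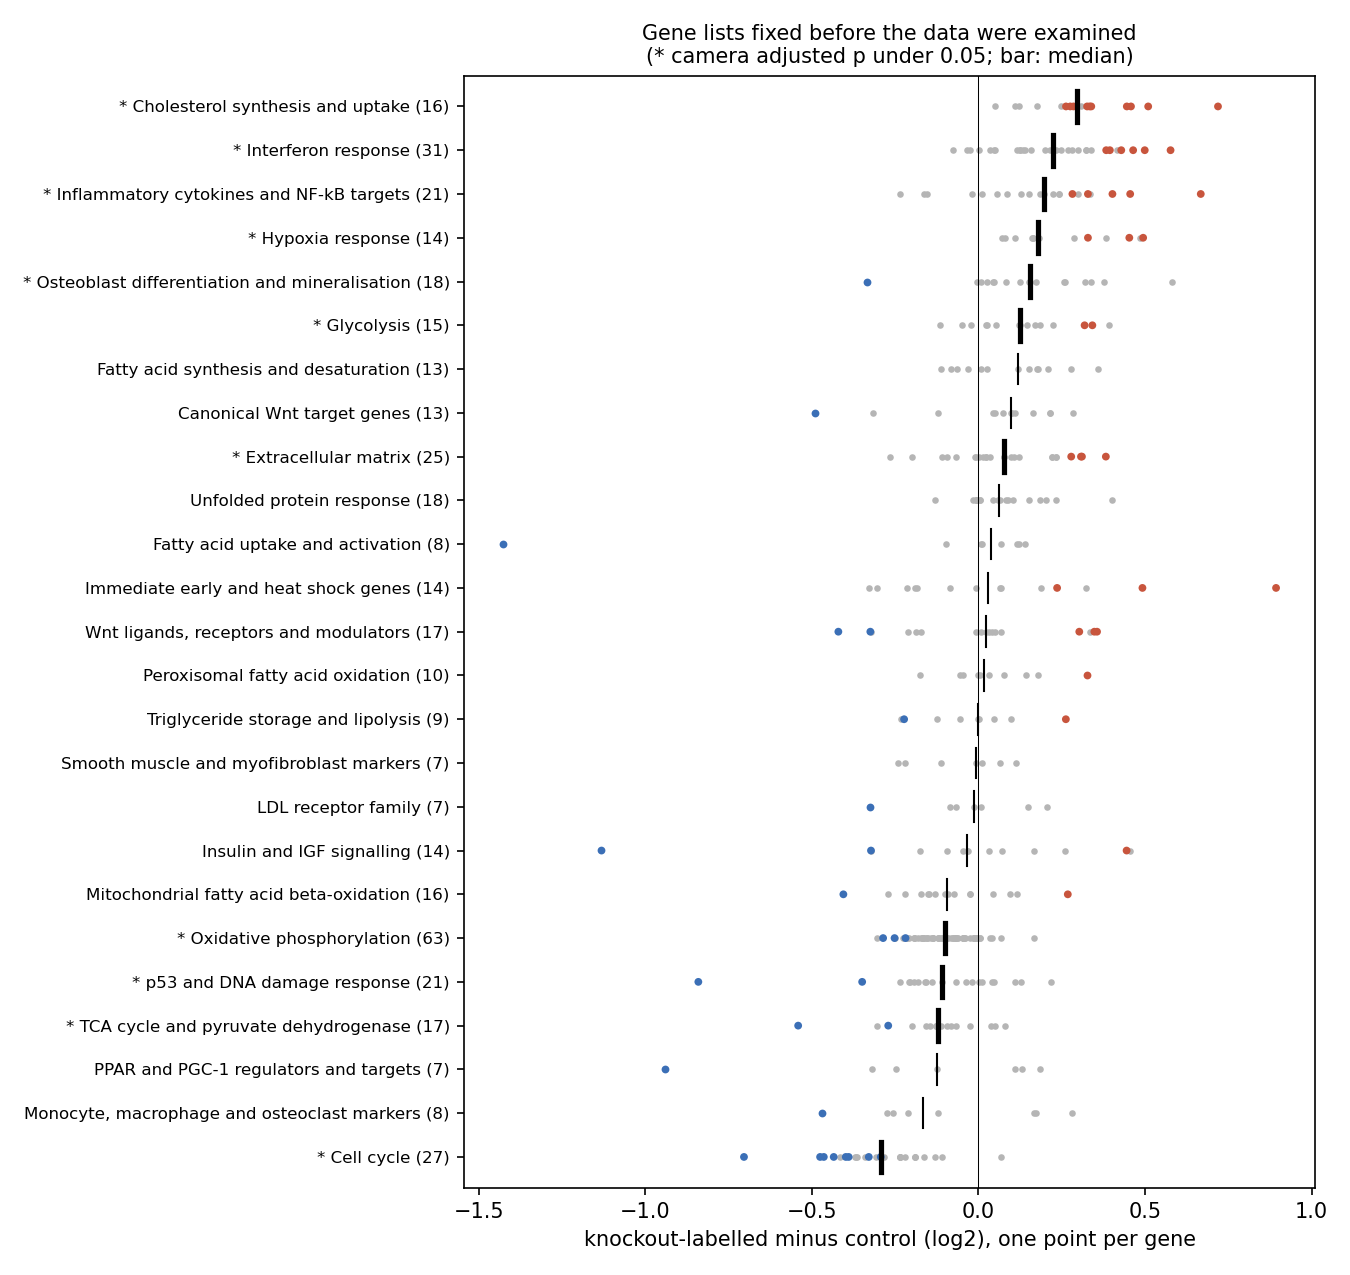
Change of each member (points, log2, knockout-labelled minus control) of the 25 lists tested, with the list median (bar) and the number of genes measured in parentheses; red and blue points are members past an adjusted p of 0.05, and an asterisk and a thick bar mark the 11 lists past an adjusted camera p of 0.05 with the preset correlation. Medians run from -0.29 for the cell cycle list to 0.30 for the cholesterol list.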

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

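The tests of other splits of the arrays on gene and list counts were fixed before their results were seen. Those of p53 targets, of virus, of macrophage markers and of undetected probes were chosen only after the results they bear on were seen. The shifts of the p53 and macrophage lists had by then been computed with the other lists. Their tests therefore describe values already at hand and are not independent. Of 238 groups of 4 arrays looked at, for named genes, list means and array measures, 13 held an array far from the other 3, where chance alone gives about 11.9 (1 in 20).

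Among list means, the mitochondrial beta-oxidation list stood at 8.83 on control array 1 and at 8.77 to 8.78 on the other control arrays. The oxidative phosphorylation list stood at 11.13 on knockout-labelled array 3, nearer the control mean of 11.16 than the other 3 knockout-labelled arrays (11.03 to 11.05). The chondrocyte list stood at 8.15 on knockout-labelled array 1 (others 7.95 to 7.98). Among genes in the knockout-labelled group, Axin2 stood at 6.04 on array 3 (others 5.46 to 5.55), Aif1l at 6.22 on array 3 (6.56 to 6.59), Cdkn1c at 6.16 on array 2 (6.82 to 6.89), Ank at 8.12 on array 2 (8.23 to 8.24) and S100a7a at 5.34 on array 1 (5.64 to 5.66). In the control group, Bglap stood at 5.04 on array 4 (4.68 to 4.72), Cd74 at 8.93 on array 2 (9.12 to 9.14), Cyp51 at 9.03 on array 2 (9.26 to 9.30), Uqcrh at 12.81 on array 2 (12.60 to 12.63) and Lipa at 8.25 on array 3 (8.35 to 8.36). Among the 561 detected probes without a gene symbol, which entered no gene test, 34 passed an adjusted p of 0.05 in limma, 19 higher and 15 lower, with changes from -0.91 to 0.82 log2.

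Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the real split, gave as many genes past the threshold: 607 genes against 0 in each of the other splits, and likewise 249 higher and 358 lower against 0; no other split came near, and 1 in 35 is the smallest share that 8 arrays allow. For the lists, 1 of the 35 splits gave as many as the real 11, while the highest of the others gave 10, with the camera test at its preset correlation. The 16 splits that exchanged 1 array per group, which keep part of the group difference, gave 2 to 10 lists, and the 18 that exchanged 2 gave 0 to 5.

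Cell cycle genes were lower as a list at the preset correlation, a call lost with an estimated correlation (0.365; adjusted p = 0.223). An ongoing p53 response to DNA damage, which Cre recombinase can set off, would raise p53 targets in the group that received Cre. If that was the knockout-labelled group, the targets go against it, since the 21 differed by -0.11 log2 (95% interval -0.17 to -0.06). Of them 7 were above 0 and 14 below, and the list's own call was lost with an estimated correlation (camera adjusted p = 0.223). In that case these values, at hand before the test was chosen, argue against such a response at day 7. They leave an earlier, finished response open. A different virus in each group cannot be told apart from the genotype. The labels tie 0 of the 8 arrays to either virus. If the Cre virus made the knockout, virus and genotype coincide on every array, and fuller labels would not separate them. A biological effect of the Lrp5 genotype remains open and untested.

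Interferon and inflammatory genes were higher as lists at the preset correlation, calls lost with an estimated correlation (0.331 and 0.0933; adjusted p = 0.223 for each). More monocytes and macrophages among the knockout-labelled cells would raise their markers by at least as much, but the 8 markers, 0 of them held by another list, differed by -0.0891 log2 (95% interval -0.22 to 0.04), below the shifts of 0.22 and 0.18 of those lists, and the abundant Lyz2 stood at 10.9 and 10.7 log2 in control and knockout-labelled arrays. The markers went both ways, with 3 of the 8 above 0: Cd53 by 0.28 log2, Ctsk (11.7 and 11.9) by 0.17 and Ctss by 0.17, none past the threshold. A different virus in each group, or a different dose of it, cannot be told apart from the genotype. Again the labels tie 0 of the 8 arrays to either virus, and virus and genotype coincide if the Cre virus made the knockout. The genotype also remains open.

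A set of 8 probes, all with a gene symbol, was detected on all 4 control arrays and stood at a detection p of at least 0.05 on all 4 knockout-labelled arrays, against 0 probes in the opposite direction. They belong to Cadm1, Ltbp1, Nrip3, Olfr372, Olfr229, Rhox1, Tinagl1 and Vpreb1. The loss is that of a probe and need not hold for the gene. The Ltbp1 probe stood at 6.78 log2 in control and 4.77 in knockout-labelled arrays. Ltbp1 was still not among the 12 largest falls, because a brighter probe stood for it in the gene test. Noise near the background is argued against, since 1 of the 35 splits, the real one, gave as many and the other splits gave 0. Viral or reporter RNA that binds the probes may account for transcripts of olfactory and B cell genes in osteoblasts, but it cannot be told apart from a genotype effect, because probe sequences were not used here and the labels tie 0 of the 8 arrays to either virus.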

How the results depend on the processing

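The number of genes past the threshold, 607 (249 higher, 358 lower), moved by over 1.5 times in total or in a direction under several settings. It was 978 (438 and 540) without background correction, 971 (437 higher) from the authors' log2 table and 965 (427 and 538) with a trended and robust prior. At an adjusted p of 0.10 it was 1079 (488 and 591), and with a signal ratio of at least 1.5 required it was 82 (17 and 65). It was 376 (131 higher) with no detection filter, where 16593 genes were tested, and 150 rose at a detection p under 0.05 on at least 1 array. With 1 array left out it lay between 327 and 722 (130 to 324 higher, 186 to 398 lower). Fewer arrays give less power, but that cannot account for the rise to 722 without control array 4. That array had the lowest array weight (0.657). The cause of that rise, and of the changes under the other settings, was not tested. The replicate numbers showed no sign of pairing the arrays. Same-numbered arrays correlated at 0.0892, -0.0325, 0.00444 and 0.00333 in their deviations from the group means, and arrays of different numbers at -0.0954 to 0.148. Of the 4 knockout-labelled arrays, 1 correlated best with its own number. The labels do not say whether the numbers mark pairs, and so few arrays cannot exclude it. With the replicate block 408 genes passed, 159 of them higher, without Acaa2, Acadvl, Atp5j2, Dgat2, Idh3a, Igf1, Lipa, Lrp4, Mcm4, Ndufb6, Thbs2, Uqcrh, Vegfa and Wnt5a of the named genes, and 10 lists passed, without the p53 list (0.0543). Of the 607 genes, 571 also passed without background correction, 572 in the authors' table and 375 with the block. Lrp5 kept its direction and stayed short of the threshold under every setting run for it, between 0.11 and 0.41 log2.

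Of the 25 lists, 8 to 14 passed under the other settings, except that 0 did with an estimated inter-gene correlation (adjusted p = 0.166 for cholesterol, 0.223 for cell cycle, interferon and oxidative phosphorylation, 0.31 for osteoblast genes). The osteoblast list was also lost with detection required on all 8 arrays (0.074) and by fry (0.0751). With 1 array left out its adjusted camera p ran from 0.00482 to 0.0873, so the call was lost in only some of those runs. The beta-oxidation and Wnt target lists stayed short of the threshold under every setting run. Lists that never passed changed direction: fatty acid uptake with detection on all 8 arrays (adjusted p = 0.523), the mean of probes (0.95), ranks (0.783) and 1 array left out (0.718 to 0.984), the LDL receptor family with 75th percentile scaling (0.946) and 1 array left out (0.718 to 0.984), and with 1 array left out also Wnt ligands (0.438 to 0.972) and insulin genes (0.631 to 0.927).

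Of 85 named genes other than Lrp5, 12 lost their call with no detection filter, 11 with the looser one, 4 with 75th percentile scaling and 3 with the mean of probes. Another 4, which never passed, changed sign; Lef1 and Bglap were detected on 0 arrays, so their values are differences between background signals. The Lef1 log2 change was 0.11 with 75th percentile scaling, 0.000381 with array weights, 0.00855 with the mean of probes and -0.0635 to 0.0531 with 1 array left out. The Bglap log2 change was -0.00763 with the mean of probes and -0.0462 to 0.126 with 1 array left out, and likewise with 1 array left out Cpt2 changed by -0.055 to 0.0294 and Alpl by -0.0358 to 0.27.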

Other observations

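The gene groups in this part were chosen after their values were seen, and so was its test, so the unadjusted camera p-values given for the groups cannot establish them as wholes. Of 14 genes of antigen presentation on MHC class I, 3 of them also in the interferon list, whose call was lost with an estimated correlation, 6 rose and 8 did not pass, among the former H2-T23 by 0.43 log2 (SE 0.09; limma adjusted p = 0.015), H2-K1 by 0.38 (0.0234), the immunoproteasome subunit Psmb10 by 0.32 (0.019) and the peptide transporter Tap2 by 0.26 (0.0475). The light chain B2m changed by 0.03. The unadjusted camera p of the group was 1.22e-07 at the preset correlation and 0.046 with an estimated one. Cd74, which belongs to MHC class II, fell 3.34-fold. The class II chain H2-Ab1 stood close to background, at 5.45 ± 0.34 log2 in control and 5.96 ± 0.27 in knockout-labelled arrays (SD, n = 4). Its difference of 0.50 did not pass the test (limma adjusted p = 0.102), so it does not tell how the class II chains changed.

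Of 25 genes of the DNA replication machinery, 12 fell and 13 did not pass; 7 of the 25 are also in the cell cycle list, whose call was lost with an estimated correlation (adjusted p = 0.223). Beside Mcm2, Mcm4 and Mcm5 the 12 included the licensing factor Cdt1 (-0.45), the flap endonuclease Fen1 (-0.48), the DNA ligase Lig1 (-0.47) and the single-strand binding protein Rpa1 (-0.42), with limma adjusted p from 0.00293 for Mcm2 to 0.0492 for Cdc45. The unadjusted camera p of the group was 3.33e-11 at the preset correlation and 0.0255 with an estimated one. Arrays were not left out in turn for the genes first named in this part, and their other probes were not compared.

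Cdkn1c, which showed the largest fall among genes detected in both groups, is an imprinted gene, and a candidate explanation is a change of imprinted genes in general. Of 28 other imprinted genes listed, only 13 were measured, and 0 of these passed the threshold. The 13 differed by -0.0266 log2 in the mean of their values (95% interval -0.0733 to 0.0201). Their changes ran from -0.24 for Dlk1 to 0.15 for Mest, with -0.05 for the abundant Igf2. Opposite changes would cancel in that mean, but no single gene of the 13 changed on the scale of the -2.56 seen for Cdkn1c. For the genes measured, this argues against a general change on that scale.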
